A study of Mus musculus with 54 samples.

How the data were processed

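Messenger RNA of liver and skeletal muscle was measured on Agilent mouse gene expression arrays in 1 colour (Cy3). The mice were males aged 44 to 45 days from 9 inbred lines, 5 of them selected for high body weight (BEHi, MUHi, ROHi, EDHi, DUHi) and 4 low or control lines (BELi, MULi, ROLi, EDLi). Per the labels' protocols, cDNA of the mice of a line was pooled, 23 mice were used in all, and each pool was hybridised to 3 arrays per tissue. The number of mice in each pool is not recorded. The line characteristic of some labels uses other codes than the titles for the ED and DU lines, and the titles were followed.

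The deposited scanner files hold linear intensity values made with Agilent Feature Extraction 10.5.1.1, per the file headers. Per the file headers, the processed intensity of a spot had its background subtracted and trends across the array removed, and dim spots received a surrogate value. The intensity was not scaled between arrays by the authors, per the file headers and the values. The deposited value table held the same intensity rounded, within 0.0072 log2 units of the scanner files. Probe positions in the files are on mm9 (NCBI37). Of 41174 distinct probes on 43379 spots other than controls, 24844 received a symbol through their accession, 6045 through their symbol and 1810 through a synonym in a table of RefSeq genes on GRCm38.p6, which was used for names only. For 8475 probes the name in the files was kept.

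Per tissue, the log2 intensity minus the array's 75th percentile was used. Spots marked as outliers by the scanner software were left out, spots of a probe were averaged, and the arrays of a pool were averaged to 1 value per line. A probe was kept when it lay well above background on at least 2 arrays of a line in at least 4 lines, and the brightest probe stood for a gene. The line was the replicate, since the 3 arrays of a pool are technical repeats. High and low lines were compared per tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The muscle minus liver difference of each line was compared between high and low lines in the same way (selection by tissue), and tested against 0 with at least 2-fold as a further condition (muscle against liver). BE, MU, RO and ED were taken as pairs of a high and a low line from the line names, and the labels do not record whether the lines of a pair share a base population. Genes at least 1.5-fold higher, or lower, in the high line of all 4 pairs were counted, and genes at least 2-fold apart within a pair with no overlap between arrays were counted without a test. DUHi, which has no partner, was set against the mean of the 4 low lines. The correlation of the high against low fold changes of both tissues was taken across genes, with the 126 splits of the 9 lines into 5 and 4 as an exact permutation test.

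34 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; fry and an estimated correlation were run beside it. The medians of the lists were also tested over the 126 exact splits. The comparisons, the lists, the rule for the genes named and the other settings to be tried were fixed before the data were examined. The rule named up to 8 genes per direction and tissue among those past the threshold, filled up with genes changed the same way in all 4 pairs; 7 genes of the growth hormone axis in liver and 8 growth or fibre genes in muscle; up to 4 members of each list with the smallest p; the 3 highest and 3 lowest genes of each pair and of DUHi; up to 4 genes per direction for selection by tissue; and the 4 genes highest in each tissue.

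4 arrays labelled liver stood apart from the other arrays of their pools. 3 of them carried values of another tissue than their label, and array EDHi 2 stood nearer to an array of another line. All 27 liver arrays were kept in the planned comparisons, no array was relabelled, and the liver comparisons were repeated on the remaining 23 arrays, an alternative chosen after seeing the data, with the rule for named genes applied to them too.

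Other alternatives were normexp background correction with quantile scaling, quantile or median scaling, the deposited value table, no filter or a filter in all lines, the mean of a gene's probes, outlier spots kept, each line or array left out, blocks for slide, origin or array number, eBayes with trend and robust options, and arrays with line as a random block or as independent samples. The slide block also left out DUHi, which shared no slide with another line. The normexp correction added an offset of 50 to the intensities. The fits were tested on simulated data with 200 changed genes drawn on the real line means and spread. Genes and lines were drawn independently of each other. For high against low in muscle, 44.8% of genes changed 2-fold, 82.1% of those changed 4-fold and 93.9% of those changed 8-fold were recovered. In liver the shares were 43.3%, 83.6% and 89.4% on 23 arrays and 19.4%, 61.2% and 77.3% on 27 arrays. For selection by tissue with 23 liver arrays they were 32.8%, 83.6% and 90.9%, and for muscle against liver 79.1%, 95.5% and 98.5%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.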

Results

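The series compared gene expression between lines of mice selected for high body weight and low or control lines, in liver and skeletal muscle of males aged 44 to 45 days. The labels give weights of 42 to 77 g for the 5 high lines and 16 to 40 g for the 4 low lines. Each line and tissue was a pool of cDNA on 3 arrays, which gave 54 arrays. The 75th percentile of the processed intensity was 319 to 587 on liver arrays and 462 to 818 on muscle arrays. Between 59.8% and 71.7% of liver spots and between 63.6% and 76.3% of muscle spots lay well above background. The number of arrays and lines limits the precision. The median SD of a gene between arrays of a pool was 0.06 log2 units in muscle and in liver. Between lines it was 0.31 among high and 0.28 among low lines in muscle, and 0.29 and 0.26 in liver on 23 arrays. All levels below are log2 intensities relative to the 75th percentile of their array.

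Markers of hepatocytes and of skeletal muscle set the tissues apart. On the 24 liver arrays of the first scan day the median of hepatocyte markers was 8.78 to 9.14 and that of skeletal muscle markers was −4.12 to 0.82. On the 27 muscle arrays these medians were −4.91 to 4.38 and 8.44 to 9.45. 3 arrays labelled liver, ROLi 2, ROLi 3 and EDHi 1, held muscle levels. Their hepatocyte median was 1.94 to 4.24 and their muscle median 8.98 to 9.16, and the muscle creatine kinase gene Ckm read 8.76 to 9.01, against −5.21 to 0.50 on the other liver arrays. Across 28189 probes, which are not independent replicates, they correlated at r = 0.995 to 0.997 with the muscle arrays of the line on their label and at 0.723 to 0.782 with the other liver arrays. These 3 arrays shared a slide, the only slide of the second scan day. A further array, labelled liver EDHi 2, was nearer to array ROLi 1 (r = 0.987) than to array EDHi 3 (r = 0.969). That r of 0.987 lay below the lowest r between arrays of a pool among the other arrays, 0.990. The array labelled EDHi 2 also had the most outlier spots, 517, and the smallest share of spots well above background, 59.8%. On 181 probes at least 8-fold apart between ROLi and EDHi in muscle, the array labelled EDHi 2 followed the ROLi minus EDHi difference at r = 0.57, array ROLi 1 at 0.57 and array EDHi 3 at −0.60. On the 23 liver arrays without these 4, ROLi and EDHi rested on 1 array each. Liver levels below are from the 23 arrays unless all 27 are named.

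**Figure D1:**
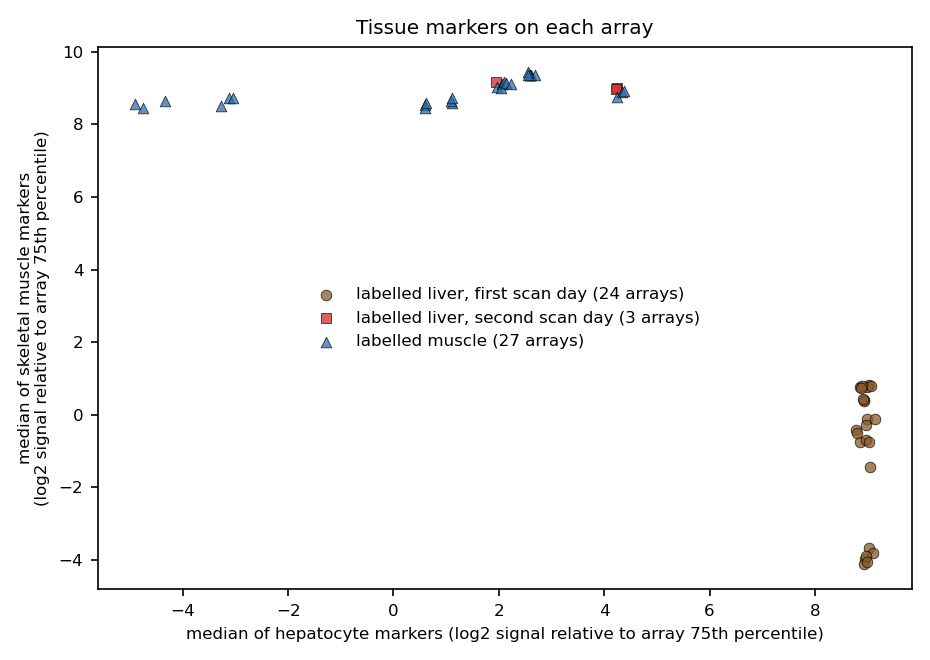
Median log2 intensity of hepatocyte markers (horizontal axis) against skeletal muscle markers (vertical axis) on each of the 54 arrays, relative to the array's 75th percentile. The 3 arrays labelled liver that were scanned on the second day lie with the 27 muscle arrays, at muscle medians of 8.98 to 9.16.

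Comparing liver of high and low lines asks which transcripts go with selection for body weight. Igf1, the growth factor that liver releases under growth hormone, was 1.69-fold higher in the high lines, at 7.26 ± 0.21 (SD, n = 5 lines) against 6.51 ± 0.11 (n = 4), and all 5 high lines lay above all 4 low lines. Igfals, whose product keeps IGF1 in circulation, read 3.90 ± 0.25 against 2.90 ± 0.37, again higher in 5 of 5. Igfbp1, which codes for a binding protein that insulin lowers, read 4.42 ± 1.78 against 8.06 ± 0.51, 12.5-fold lower and below all low lines in 5 of 5 high lines. Estrogen sulfotransferase Sult1e1 was 27.1-fold lower, at −3.90 ± 0.95 against 0.86 ± 1.44, again in 5 of 5. Without ROHi the log2 difference of Igfbp1 was −2.91 in place of −3.64, and without MULi that of Sult1e1 was −5.45 in place of −4.76. With normexp correction and quantile scaling that of Sult1e1 was −2.41. None of these differences passed the test over all genes.

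In the list of the growth hormone and IGF axis, 13 of 26 members were higher and 13 lower in the high lines, and the list did not lean either way (camera, adjusted p = 0.916). On the 23 arrays 6 members passed limma when adjusted over the list alone, and on all 27 arrays 0 did. The 6 were Igf1 with a log2 fold change of 0.76 (adjusted p = 0.00721), Igfals with 0.99 (0.00956), Igfbp1 with −3.64 (0.0127), Igfbp6 with −0.998 (0.0164), the insulin receptor adaptor Grb10 with 1.36 (0.0280) and Igfbp2 with −1.73 (0.0383). Over all genes their adjusted p were 0.221, 0.232, 0.290, 0.383, 0.427 and 0.486. Socs2, a feedback inhibitor of growth hormone signalling, had a log2 fold change of 1.69 (SE 0.60, adjusted p = 0.546), Igfbp3 of 0.36 (SE 0.31, 0.844) and the receptor gene Ghr of 0.21 (SE 0.14, 0.779). Over 4 probes the log2 fold change of Igf1 was 0.25 to 0.93. Between probes that of Socs2 was 0.67 to 1.69, of Igfbp3 −0.08 to 0.36 and of Ghr −0.02 to 0.25. The probe of Igf1 lies on chromosome 10 at 87393516 to 87393575 and that of Igfbp1 on chromosome 11 at 7102442 to 7102501. In the list of body size genes, 4 of 24 passed on 23 arrays and 0 on 27 when adjusted over the list alone, Igf1 (0.00501), the leptin receptor gene Lepr with −1.73 (0.00501), glypican 3 (Gpc3) with −0.92 (0.00501) and Igf2bp2 with −1.08 (0.0115). That list did not pass as a whole (adjusted p = 0.0897). With normexp correction and quantile scaling the log2 fold changes of Lepr and Gpc3 were −0.39 and −0.23, and without EDLi that of Socs2 was 1.01.

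Other liver genes named by the same rule lay at least 1.5-fold apart the same way in all 4 pairs. Gbp8, an interferon-inducible GTPase gene, read 3.96 ± 0.30 against 0.80 ± 1.02 (log2 fold change 3.16, SE 0.42, adjusted p = 0.141). Serpina9 had a log2 fold change of 2.06 (SE 0.38, 0.221) and the oxysterol hydroxylase gene Cyp7b1 of 2.33 (SE 0.61, 0.427). Apol10a stood at 4.77 (SE 1.09, 0.308), with 4 of 5 high lines above all low lines, and at 2.22 with normexp correction and quantile scaling, 5.69 without ROHi and 4.12 without EDHi. Ppp1r3g, which targets a phosphatase to glycogen, stood at −4.04 (SE 1.02, 0.410) and the hydroxylase gene Cyp39a1 at −2.63 (SE 0.65, 0.387). Ppp1r3g was at −2.95 with normexp correction, −4.69 without BELi and −3.27 without ROHi, and Cyp39a1 at −2.03 without ROHi. For Sult1e1, on chromosome 5 at 88005187 to 88005246, the log2 fold change was −4.76 (SE 0.70, 0.204).

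**Figure D2:**
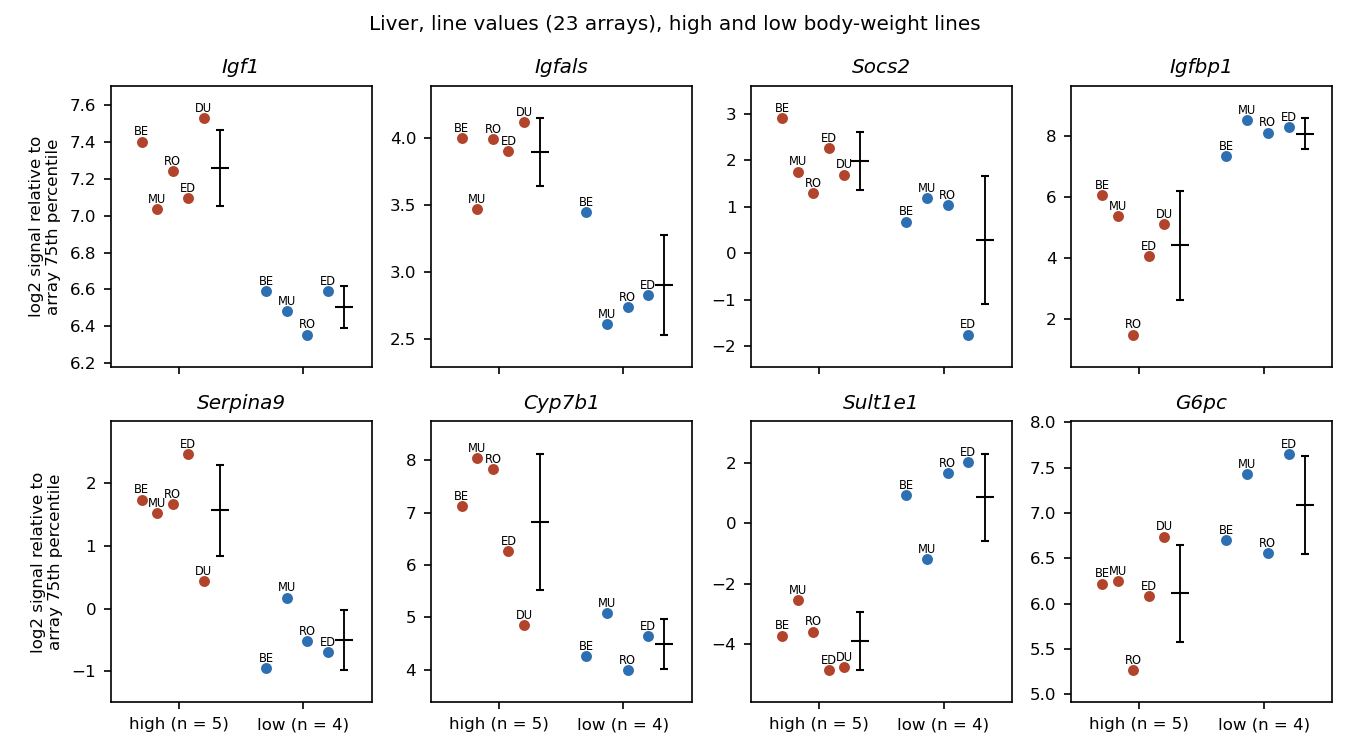
Level of 8 liver genes in each line (points, log2 intensity relative to the array's 75th percentile, 23 liver arrays) with the mean and SD of the 5 high and 4 low lines. Igf1 and Igfals were higher and Igfbp1 and Sult1e1 lower in all 5 high lines than in any low line; no gene shown passed the test over all genes.

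With limma, 0 of 17971 genes passed on the 23 liver arrays, with 1427 at an unadjusted p under 0.05 (625 higher, 802 lower) where chance alone gives 899, and a lowest adjusted p of 0.0648. On all 27 arrays 0 of 17963 genes passed, with 461 at an unadjusted p under 0.05 where chance gives 898. That count was 276 without ROHi, 298 without DUHi, 720 without ROLi and 843 without EDHi. With single arrays and line as a random block, limma called 298 genes on 23 arrays and 4 on 27. That fit still counts technical arrays towards its precision, while selection varies only between lines. Without BELi 4 genes passed on the 23 arrays, Gbp8 among them (adjusted p = 0.0342), without EDHi 2, and without MUHi or EDLi 1 each.

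Lists of liver metabolism leaned both ways at the preset correlation, cholesterol synthesis up and glucose, amino acid and fatty acid breakdown down. Of 26 genes of cholesterol synthesis, 24 were higher in the high lines, with a median log2 fold change of 0.24 (camera, adjusted p = 0.000171). Examples were the synthase gene Hmgcs1 with 1.03 (SE 0.26) and Mvd with 1.27 (SE 0.51). Of 30 genes of the unfolded protein and heat shock response 20 were higher, with a median of 0.23 (0.00665), among them Sdf2l1 with 1.56 (SE 0.34), which passed when adjusted over the list alone on 23 arrays (0.0342) but not on 27, and Hyou1 with 1.21 (SE 0.39), or 0.39 as the mean of its probes. Of 23 genes of gluconeogenesis and amino acid catabolism 18 were lower, with a median of −0.36 (3.07e-05). Glucose-6-phosphatase (G6pc) had −0.97 (SE 0.32), the coactivator gene Ppargc1a −1.57 (SE 0.49) and Hpd, for tyrosine breakdown, −0.63 (SE 0.18). Of 37 genes of fatty acid oxidation and PPAR alpha targets 29 were lower, with a median of −0.24 (0.000262), as for Acadm with −0.53 (SE 0.14), Cd36 with −1.25 (SE 0.38) and Angptl4 with −1.06 (SE 0.36). Of 51 genes of oxidative phosphorylation 44 were lower, with a median of −0.09 (0.00584), Sdhd among them with −0.29 (SE 0.14). With an estimated correlation none of the 10 lists that passed in liver was called, at adjusted p = 0.702 to 0.738, and fry called 0 of 34 lists (lowest adjusted p = 0.477).

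Genes with a sex difference in mouse liver also leaned. Of 27 male-biased genes 20 were higher in the high lines, with a median of 0.15 (camera, adjusted p = 0.0101), and of 29 female-biased genes 21 were lower, with a median of −0.64 (0.0269). The adjusted p with an estimated correlation was 0.702 for the male-biased and 0.738 for the female-biased genes. DUHi did not share the lean throughout. A1bg (11.02) and Hao2 (6.14) of the female-biased list were among its 3 highest liver genes against the mean of the low lines. Its male-biased median was the lowest of the high lines, at −0.33 against 0.18 for the next. On 23 arrays 3 female-biased genes passed when adjusted over the list alone and on 27 arrays 0 did, where the list was not called either (0.129). The 3 were Sult1e1, Cyp39a1 and Cyp2c40, and the last went the other way, with a log2 fold change of 0.68 (SE 0.14). Of 29 acute phase genes 24 were higher, with a median of 0.24 (0.0116, and 0.702 with an estimated correlation), such as Itih3 with 0.70 (SE 0.19), while the metallothionein gene Mt1 had −2.31 (SE 0.82), or −2.98 without EDHi. Of 36 cell cycle genes 28 were higher, with a median of 0.26 (0.0297, and 0.738 with an estimated correlation), the helicase gene Mcm6 at 1.51 (SE 0.52). All 14 markers of pancreatic acinar cells were lower, with a median of −1.83 (0.00138, and 0.702 with an estimated correlation) and Cela2a at −2.53 (SE 1.12), or −1.01 with normexp correction, −1.93 without BEHi, −1.76 without MULi and −3.52 without EDLi. Relative to the mean of the lines, the acinar median was −4.86 in BEHi, 2.17 in BELi and 4.26 in MULi, so single pools differed more than the groups.

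The other 24 lists had adjusted p of 0.0736 to 0.916 in liver. Besides the 2 lists named above, they were fatty acid synthesis, bile acid synthesis and transport, xenobiotic metabolism, the circadian clock, fast and slow muscle fibre, myostatin signalling, muscle atrophy, muscle development, extracellular matrix, imprinted growth genes, immediate early genes, interferon response, MHC genes, and markers of immune cells, adipocytes, blood, endothelium, cholangiocytes and stellate cells, nerve, hepatocytes and skeletal muscle. Median, mean and test differed in sign for bile acid synthesis, MHC genes and nerve markers. A call ended without BEHi for male-biased genes (0.0703), the unfolded protein response (0.0834), acinar markers (0.0703) and the cell cycle (0.216). It ended without BELi for female-biased genes (0.113) and the unfolded protein response (0.0517), and without MUHi for female-biased genes (0.362), fatty acid oxidation (0.0553), acute phase genes (0.169) and the cell cycle (0.0524). It ended without MULi for acinar markers (0.113) and the cell cycle (0.178), without ROHi for male-biased (0.0536) and female-biased genes (0.0834), and without ROLi for female-biased genes (0.0867) and the cell cycle (0.0524). It ended without EDHi for acute phase genes (0.0768), without EDLi for these (0.0548), oxidative phosphorylation (0.0509) and the cell cycle (0.419), and without DUHi for the cell cycle (0.0577). Processing ended it for male-biased genes with normexp correction (0.129) and quantile scaling (0.0856), acute phase genes with quantile scaling (0.0856) and female-biased genes with the mean of a gene's probes (0.0628). For the cell cycle it ended with normexp correction (0.143), a filter in all lines (0.0611) and a slide block that also left out DUHi (0.0530). Within the 5 slides that held both groups, high minus low medians were 0.03 to 0.45 for cholesterol synthesis, −0.55 to −0.01 for fatty acid oxidation, −0.32 to −0.02 for oxidative phosphorylation and −0.58 to 0.03 for gluconeogenesis. They were 0.15 to 0.41 for male-biased genes, −2.57 to −0.19 for female-biased genes, −0.21 to 0.82 for the unfolded protein response, −0.35 to 0.61 for acute phase genes, −0.57 to 0.55 for the cell cycle and −7.28 to 2.24 for acinar markers.

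On all 27 liver arrays 14 lists passed at the preset correlation and 0 with an estimated correlation (adjusted p = 0.766 to 0.807). Cholesterol synthesis (8.09e-09), immune markers (3.80e-05), the unfolded protein response (0.00127), male-biased genes (0.00225), interferon response (0.0184), the cell cycle (0.0192) and acute phase genes (0.0361) were higher in the high lines. Oxidative phosphorylation (3.84e-07), acinar markers (0.000771), muscle atrophy genes (0.0184), extracellular matrix (0.0184), body size genes (0.0351), the circadian clock (0.0358) and slow muscle fibre genes (0.0361) were lower. These values include the 3 arrays at muscle levels of skeletal muscle markers. The list of gluconeogenesis, with an adjusted p of 0.368, was not among them, and its median and test differed in sign. A slide block, which also left out DUHi, ended the calls of immune markers (0.208), interferon response (0.632), acute phase genes (0.383) and extracellular matrix (0.632). It also ended those of slow fibre genes (0.632), the clock (0.196), atrophy genes (0.144) and body size genes (0.283). Of these, only immune markers and extracellular matrix kept their call without DUHi alone. An origin block ended those of acute phase genes (0.0784), the clock (0.175), slow fibre genes (0.263), atrophy genes (0.0605), interferon response (0.0843) and body size genes (0.138). Without ROLi the extracellular matrix list passed as higher in the high lines (0.0378), and the calls ended for male-biased genes (0.390), acute phase genes (0.248), the clock (0.283), slow fibre genes (0.570), atrophy genes (0.0653), oxidative phosphorylation (0.0724) and interferon response (0.493). A call ended without BEHi for extracellular matrix (0.146), the cell cycle (0.118) and acinar markers (0.0582), without BELi for acinar markers (0.0527) and body size genes (0.0623), and without MUHi for acute phase genes (0.331), the clock (0.0566) and slow fibre genes (0.190). Without MULi it ended for the clock (0.0817), slow fibre genes (0.0698), the cell cycle (0.250), acinar markers (0.298) and body size genes (0.0844), and without ROHi for acute phase genes (0.0566), extracellular matrix (0.0595) and interferon response (0.113). Without EDLi it ended for atrophy genes (0.0528), the cell cycle (0.631) and interferon response (0.237). Without DUHi it ended for acute phase genes (0.0577), the clock (0.237), slow fibre genes (0.270), atrophy genes (0.0517), the cell cycle (0.0517), interferon response (0.0561) and body size genes (0.0940). Normexp correction ended it for the cell cycle (0.115) and body size genes (0.0553), a filter in all lines for the clock (0.0588) and slow fibre genes (0.0779), and no filter (0.0549) or the mean of a gene's probes (0.0503) for body size genes.

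**Figure D3:**
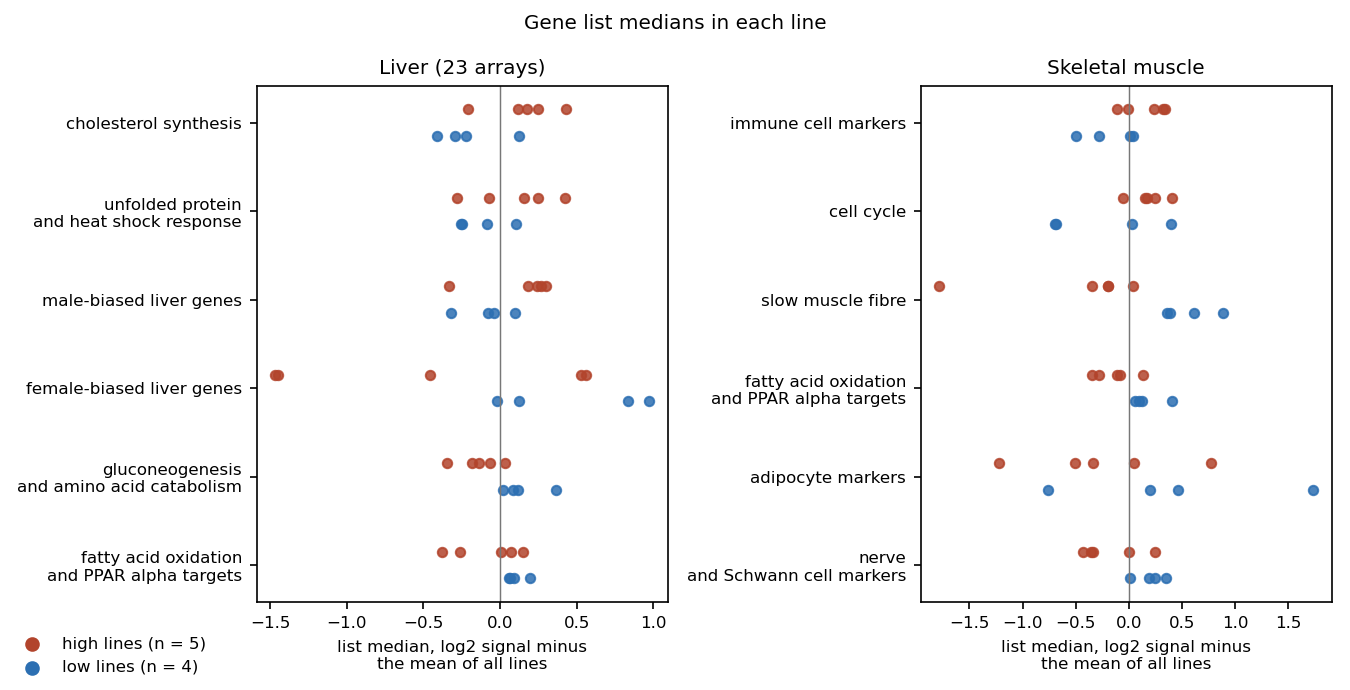
Median log2 fold of 6 lists in liver (23 arrays) and 6 lists in muscle for each line, relative to the mean of the lines, for the 5 high and 4 low lines. The median high minus low difference of fatty acid oxidation genes was −0.24 in liver and −0.33 in muscle (adjusted p = 0.702 and 0.240 with an estimated correlation). In liver the groups overlapped, with DUHi at 0.15 above BELi, MULi and ROLi, and ROHi at 0.07 above BELi and ROLi.

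In skeletal muscle, genes of slow contractile fibres leaned lower in the high lines as a list (camera, adjusted p = 1.93e-15). With an estimated correlation camera did not make this call (adjusted p = 0.240). Over exact splits of the lines the adjusted p was 0.337, in a test that 1 list alone could not pass after adjustment. The slow myosin gene Myh7 read 1.77 ± 2.82 (SD, n = 5 lines) against 5.97 ± 1.19 (n = 4), 18.4-fold lower, and lay below all low lines in 4 of 5 high lines. Its partner light chain gene Myl2 was 15.9-fold lower, at 0.13 ± 3.03 against 4.12 ± 1.00, in 5 of 5. Ppara, a regulator of fatty acid oxidation, read −0.55 ± 0.57 against 1.01 ± 0.50, again lower in 5 of 5. The chemokine gene Ccl12 was higher in 5 of 5, at −2.41 ± 0.48 against −4.36 ± 0.57, as was the spindle gene Spag5, at 0.97 ± 0.65 against −1.10 ± 0.42. Without MUHi the log2 differences of Myh7 and Myl2 were −3.15 and −2.83 in place of −4.20 and −3.99, without BEHi −4.92 and −4.61, and without EDLi that of Myh7 was −4.80. With normexp correction and quantile scaling that of Ccl12 was 0.78 in place of 1.95 and that of Myl2 −3.38, and as the mean of its probes that of Spag5 was 1.21 in place of 2.07. None of these genes passed the test over all genes.

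For Myh7, on chromosome 14 at 55589526 to 55589585, the log2 fold change was −4.20 (SE 1.33, adjusted p = 0.729), with −1.92 in the BE pair, −8.96 in MU, −3.07 in RO and −3.75 in ED. For Myl2 it was −3.99 (SE 1.39, 0.766), for the slow troponin gene Tnnt1 −2.68 (SE 0.87, 0.746) and for Myoz2 −2.26 (SE 0.70, 0.729). It was 2.07 for Spag5 (SE 0.34, 0.384), 1.95 for Ccl12 (SE 0.32, 0.384) and 2.27 for the calcium channel subunit gene Cacna2d4 (SE 0.46, 0.629), or 1.62 with normexp correction. Without MUHi it was −1.96 for Tnnt1 and −1.58 for Myoz2. Genes of muscle growth showed smaller values. Myostatin (Mstn), a brake on muscle growth, had 0.24 (SE 0.28, 0.893), Igf1 0.49 (SE 0.31, 0.841), Igf2 0.23 (SE 0.26, 0.894) and the receptor gene Igf1r −0.36 (SE 0.16, 0.803). Follistatin (Fst) had −0.43 (SE 0.22, 0.832). The myostatin receptor gene Acvr2b had 0.25 (SE 0.31, 0.898), which became −0.01 without BELi, and the fast myosin gene Myh4 had 0.20 (SE 0.26, 0.901), which became −0.03 under quantile scaling and −0.01 with normexp correction before it. Sult1e1 stood at 1.66 (SE 0.55, 0.754) in muscle, or 1.07 with normexp correction.

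**Figure D4:**
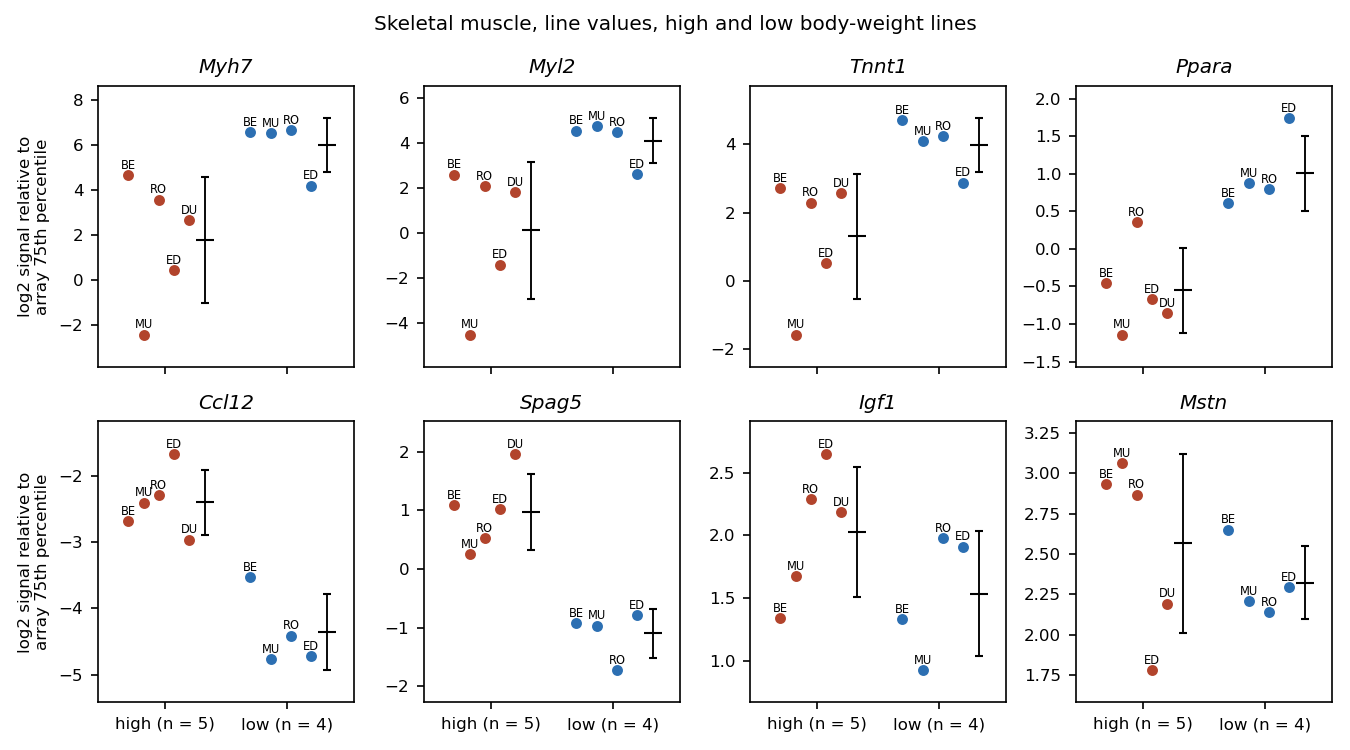
Level of 8 muscle genes in each line (points, log2 intensity relative to the array's 75th percentile, 27 muscle arrays) with the mean and SD of the 5 high and 4 low lines. Myl2, Tnnt1 and Ppara were lower and Ccl12 and Spag5 higher in all 5 high lines than in any low line; no gene shown passed the test over all genes.

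With limma, 0 of 20164 muscle genes passed, with 1247 at an unadjusted p under 0.05 (762 higher, 485 lower) where chance gives 1008, and a lowest adjusted p of 0.269. The balance turned with scaling, to 559 higher and 679 lower with quantile scaling and 582 and 633 with normexp correction before it. With single arrays and line as a random block, a fit that still counts technical arrays towards its precision, 207 passed. On line values without EDHi 6 passed.

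The slow fibre list had the smallest p of the 34 lists in muscle. Of 21 members 19 were lower in the high lines, with a median log2 fold change of −0.92 (camera, adjusted p = 1.93e-15, and 0.240 with an estimated correlation), and 11 passed when adjusted over the list alone. Besides the genes above these included Tnni1 with −2.08 (SE 0.52), Tnnc1 with −2.25 (SE 0.58), Myh6 with −2.22 (SE 0.55; −3.11 as the mean of its probes) and the calcium pump gene Atp2a2 with −1.22 (SE 0.30). Over 3 probes the log2 fold change of Atp2a2 was −1.22 to −0.29. Of 36 genes of fatty acid oxidation 33 were lower, with a median of −0.33 (4.01e-13, and 0.240 with an estimated correlation), and Ppara with −1.56 (SE 0.33) and Acot1 with −1.15 (SE 0.25) passed when adjusted over the list alone. Acaa2 had −0.60 (SE 0.19). Of 28 fast fibre genes 24 were higher, with a median of 0.23 (0.0241, and 0.804 with an estimated correlation), Actn3 at 0.34 (SE 0.14) and Ckm at 0.37 (SE 0.17), while Smtnl1 had −1.24 (SE 0.41). Of 20 skeletal muscle markers 19 were higher, with a median of 0.24 (0.00941, and 0.804 with an estimated correlation). Under quantile scaling the fast fibre and skeletal muscle lists had adjusted p of 0.770 and 0.661. Of 31 genes of atrophy, FOXO and mTOR 22 were lower, with a median of −0.02 and a mean of −0.18 (0.00482, and 0.629 with an estimated correlation), Klf15 at −0.79 (SE 0.25) and Ddit4 at −1.85 (SE 0.67; −2.56 without BELi).

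Markers of other cell types in muscle also differed. Of 31 immune markers 30 were higher in the high lines, with a median of 0.43 (camera, adjusted p = 3.98e-05, and 0.366 with an estimated correlation), among them the T cell gene Cd3g with 0.63 (SE 0.14). At the lowest of the other settings run, the value of Cd3g was 0.09. Of 38 cell cycle genes 35 were higher, with a median of 0.42 (0.00021, and 0.629 with an estimated correlation). All 13 adipocyte markers were lower, with a median of −0.57 (0.000109, and 0.629 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, stood at −2.14 (SE 1.70), and at −1.17 without MUHi, −3.78 without MULi, −1.42 without EDLi and −2.84 without DUHi. Of 15 nerve and Schwann cell markers 13 were lower, with a median of −0.32 (3.86e-05, and 0.453 with an estimated correlation). Of 20 endothelial markers 16 were lower, with a median of −0.28 (9.83e-05, and 0.495 with an estimated correlation), as for Robo4 with −0.44 (SE 0.15). Of 30 interferon response genes 22 were lower, with a median of −0.15 (0.00576, and 0.629 with an estimated correlation), as for Gbp2 with −0.49 (SE 0.12).

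3 lists of liver metabolism were called lower in muscle of the high lines at the preset correlation, gluconeogenesis (median −0.18, adjusted p = 0.00941), fatty acid synthesis (−0.22, 0.0164) and xenobiotic metabolism (−0.08, 0.0173), as were immediate early genes (−0.18, 0.0291). With an estimated correlation their adjusted p were 0.804, 0.804, 0.816 and 0.804. Across the settings run, lines left out included, the median ranged from −0.99 to 0.43 for gluconeogenesis and from −0.59 to 0.37 for xenobiotic metabolism, so their direction was not stable. Hepatocyte transcripts were present in the muscle pools of 7 lines. Over 46 liver probes the median share of a line's own liver level was 0.258% in BEHi, 0.174% in BELi, 0.830% in ROHi, 2.29% in ROLi, 0.564% in EDHi, 0.509% in EDLi and 0.752% in DUHi. These probes were chosen as bright in MUHi and MULi liver and above background on none of their muscle arrays. The low r between muscle and liver in MUHi and MULi, 0.262 and 0.0409, was largely fixed by that choice. The median of hepatocyte markers, not chosen this way, was −3.12 in MUHi and −4.76 in MULi muscle. In the 7 other lines it was 0.61 (BELi) to 4.34 (ROLi). The hepatocyte list itself had a median of 0.25 between high and low lines (0.761). The albumin gene Alb ranged from −3.21 in MULi to 8.06 in ROLi muscle.

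The other 19 lists had adjusted p of 0.0505 to 0.919 in muscle, and median, mean and test differed in sign for 12 of these. They were the growth hormone axis, male-biased and female-biased genes, cholesterol and bile acid synthesis, acute phase, the circadian clock, myostatin signalling, muscle development, extracellular matrix, oxidative phosphorylation, imprinted growth genes, the unfolded protein response, MHC genes, body size genes, and markers of blood, cholangiocytes and stellate cells, hepatocytes and acinar cells. Adjusted over the list alone, Mgp (extracellular matrix), H2-DMa (MHC), Cela3b (acinar) and Gpc3 (body size) passed. A call ended without BELi for interferon response (0.137), fast fibre genes (0.260) and skeletal muscle markers (0.192). It ended without MUHi for fatty acid synthesis (0.391), gluconeogenesis (0.456), xenobiotic metabolism (0.701) and immediate early genes (0.0750), and without MULi for fast fibre genes (0.112), skeletal muscle markers (0.0616) and immediate early genes (0.304). Without ROHi it ended for fatty acid synthesis (0.0575), fast fibre genes (0.118), skeletal muscle markers (0.0842), interferon response (0.0733) and immediate early genes (0.270). Without ROLi it ended for fatty acid synthesis (0.253), gluconeogenesis (0.633), xenobiotic metabolism (0.633), interferon response (0.112) and immediate early genes (0.217). Without EDLi it ended for fatty acid synthesis (0.275), gluconeogenesis (0.103), xenobiotic metabolism (0.160), the cell cycle (0.0843) and immediate early genes (0.0641), and without DUHi for fast fibre genes (0.164) and skeletal muscle markers (0.0553). Quantile scaling ended it for fatty acid synthesis (0.0569), xenobiotic metabolism (0.0936) and immediate early genes (0.0659), and normexp correction for immediate early genes (0.0831), fast fibre genes (0.596) and skeletal muscle markers (0.541). A slide block, which also left out DUHi, ended it for fast fibre genes (0.213) and skeletal muscle markers (0.165). Leaving out DUHi alone ended both calls too. Within the 6 muscle slides that held both groups, high minus low medians were −1.76 to −0.53 for slow fibre genes, −0.65 to −0.14 for fatty acid oxidation, −0.66 to −0.16 for nerve markers, −0.07 to 0.80 for immune markers, −0.52 to 1.24 for the cell cycle, −1.74 to 0.63 for adipocyte markers and −0.66 to 0.18 for endothelial markers.

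Over the 126 exact splits of the lines, the list medians of slow fibre genes (exact p = 0.0238), immune markers (exact p = 0.0317), fatty acid oxidation and endothelial markers (exact p = 0.0397 each) in muscle lay far out, with an adjusted p of 0.337 over the 34 lists. In liver gluconeogenesis and the atrophy list had the smallest exact p, 0.0159 each (adjusted p = 0.270). The smallest exact p these splits allow is 0.00794.

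Pairs of a high and a low line that share the first letters of their names were set against each other to find genes that differ the same way in each pair. The labels do not record whether the lines of a pair come from the same base population. In muscle 114 genes were at least 1.5-fold apart the same way in all 4 pairs, 47 higher and 67 lower, Myh7 and Myl2 among the lower. In liver 116 genes did so on 23 arrays (42 higher, 74 lower), Igfbp1 and Sult1e1 among the lower, and 47 on 27 arrays (16 higher, 31 lower). In simulated data, 100 genes that had not been changed met this condition in muscle, 74 in liver on 23 arrays and 165 on 27 arrays. The simulation drew genes and lines independently, unlike the real data. In the real data with the sign of some pairs turned, 12 to 42 genes met it in muscle. In liver 24 to 65 did on 23 arrays and 10 to 184 on 27 arrays. These 8 sign patterns are too few for a test. Within single pairs many more genes were at least 2-fold apart with no overlap between arrays. These were 1264 in BE, 1315 in MU, 2563 in RO and 1512 in ED in muscle, and 821 in DUHi against the low lines. In liver on 23 arrays they were 1265, 1469, 1651, 1790 and 1382, and on 27 arrays 1254, 1470, 4040, 2308 and 1679. A pair has 1 pool per line, so these differences have no replicate check.

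The largest differences within pairs were read on 1 probe per gene. In BE liver the digestive enzyme genes Cpb1 (−9.51), Cela3b (−9.17) and Cpa1 (−9.14) were lowest in the high line. No BEHi array held them above background, and against the background level the log2 differences were −8.06, −8.86 and −7.72. In BE muscle the secretory genes Fcgbp (10.48), Tgm4 (10.46) and Spink1 (10.05) were highest. Whether these transcripts came from muscle or from other tissue in the pool was not tested. In MU muscle Myl2 (−9.27) and Myh7 (−8.96) were among the 3 lowest. In ED liver the renin genes Ren2 and Ren1 stood at −9.55 (−8.12 against the background level) and −7.68. DUHi liver had A1bg at 11.02 and the clock gene Ciart at −6.03 against the low lines, and DUHi muscle had Ucp3 at −3.47. 16 genes were at least 16-fold apart in the same pair and direction in both tissues, in 19 gene and pair combinations, 11 higher and 8 lower. Pdxdc1 stood at −9.67 in liver and −8.59 in muscle in BE, but at 9.05 and 8.24 in MU and at 9.27 and 9.09 in ED. The other probe of Pdxdc1 differed by much less, by 1.49 and 1.76 in size in BE, 2.00 and 1.93 in MU and 1.63 and 1.67 in ED, so the size for the gene is not settled. Thumpd1 stood at 9.60 (7.36 against the background level) and 10.36 in RO. Another probe of the gene was measured for 13 of the 19 combinations, and in 6 of them, Itch, Ap2b1, 5830417I10Rik, Mrpl35 and Ptprg in both MU and ED, that probe differed by less than 2-fold in both tissues, so these differences rest on 1 probe. Only Padi4 in BE stayed past 16-fold on its other probes, at 5.29 in liver and 5.85 in muscle in size. Trappc13 in MU stood at 4.72 and 4.44, but at 1.41 and 1.23 in size on its other probe.

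Whether selection changed both tissues alike was asked with the difference between tissues in each line. Sult1e1 had the largest contrast, lower in liver of the high lines by −4.76 and higher in muscle by 1.66, a difference of 6.43 (SE 0.68), with an adjusted p of 0.0860 by limma. Tmem189 had a difference of 1.37 (adjusted p = 0.214) and Tmem82 of −1.85 (0.214). Gbp8, at 3.16 in liver and 1.00 in muscle, had −2.16 (0.379). With limma 0 of 17450 genes passed on the 23 liver arrays, with 1184 at an unadjusted p under 0.05 where chance gives 872.5. On 27 arrays 0 of 17514 passed, with 421 at an unadjusted p under 0.05 (229 without ROHi, 263 without DUHi, 825 without EDHi). Without ROHi 2 genes passed on the 23 arrays. Across 17446 genes, which are not independent, the high against low fold changes of liver and muscle correlated at r = 0.424 on 23 liver arrays (exact permutation p = 0.0635, two-sided), and the other splits of the lines gave 0.212 to 0.472. On 27 arrays r was 0.405 across 17512 genes (exact permutation p = 0.103), with other splits at −0.198 to 0.460. Liver transcripts in the muscle pools can raise such an r without a shared response. On the 46 liver probes, a line's liver deviation from the mean of the lines other than MUHi and MULi recurred in its muscle. There r was 0.736 (BEHi) to 0.971 (DUHi). How much of the r across all genes comes from this was not tested.

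Muscle against liver checked the labels and the range of the assay. The fast fibre gene Actn3 read 9.02 ± 0.25 (SD, n = 9 lines) in muscle and −3.18 ± 2.22 in liver, a difference of 12.20 (adjusted p = 3.29e-08). The parvalbumin gene Pvalb (12.04), Ampd1 (11.66) and Myom2 (11.27) followed. Among the highest on the liver side were Ftcd (−9.17), for histidine breakdown, and the cytochrome P450 genes Cyp2c39 (−9.11) and Cyp2a5 (−9.08). On 23 liver arrays limma called 9772 of 20676 genes at least 2-fold, 5397 higher in muscle and 4375 higher in liver. On 27 arrays it called 8922 of 20607, 4986 and 3936. The median of all genes lay 0.11 above 0 on 23 arrays and 0.12 on 27 arrays.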

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

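The splits of the lines were planned before the data were examined; the tests of the 4 liver arrays, of the slow fibre genes and of the liver gluconeogenesis genes, and all values on 23 liver arrays, were chosen only after the results were seen.

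In liver of the low lines, EDLi lay far above the others for Hpd (gap over range 0.883, 7.82 against 7.20 for the next line), BELi far above for Cyp2c40 (0.901, 7.40 against 7.23) and for the cell cycle median (0.838, 0.76 against −0.33), BELi far below for Gpc3 (0.908, −3.47 against −3.08) and ROLi far above for Lepr (0.925, −1.94 against −3.51). In liver of the high lines, ROHi lay far below the others for Lepr (0.762, −5.25 against −4.90), DUHi far above for Cd36 (0.711, 1.00 against −0.32) and far below for the male-biased median (0.810, −0.33 against 0.18). In muscle of the low lines, EDLi lay far below the others for the slow fibre genes Myh7 (0.953, 4.18 against 6.52), Myl2 (0.886, 2.63 against 4.51) and Myh6 (0.878, 0.14 against 1.93), and MULi far below for Ucp1 (0.851, −2.93 against 3.08). In muscle of the high lines, MUHi lay far below the others for Myoz2 (0.834, −0.88 against 2.24) and for the slow fibre median (0.790, −1.78 against −0.34). These were 14 of 184 groups of lines tested, and chance marks about 1 in 20 groups.

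The difference between high and low lines itself differed between muscle and liver for 7 lists with camera, in the muscle minus liver values of each line on 23 liver arrays. The median differences were −0.28 for cholesterol synthesis (adjusted p = 1.06e-05), −0.0204 for fatty acid oxidation (0.0299), −0.69 for slow fibre genes (4.95e-09), −0.29 for the unfolded protein response (1.06e-05), −0.27 for interferon response (0.000112), −0.37 for nerve markers (0.00112) and 2.27 for acinar markers (0.0211). With an estimated correlation the adjusted p were 0.811, 0.811, 0.655, 0.655, 0.736, 0.655 and 0.922.

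4 arrays labelled liver stood apart from the other arrays of their pools. A signal shift of the second scan day was argued against, because skeletal muscle markers on its 3 arrays lay at least 8.16 log2 units above those of the other liver arrays while hepatocyte markers lay lower. Muscle RNA of the line on the label is a candidate explanation for these 3, with a lowest r of 0.995 to the muscle arrays of the same line. Liver RNA of ROLi is one for the array labelled EDHi 2, with r = 0.57 to the ROLi minus EDHi difference. Its r with array ROLi 1, 0.987, lay below the lowest r between arrays of a pool, 0.990, so this match is not settled. Where an exchange would have happened, at hybridisation or in the records, was not tested.

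Slow fibre genes leaned lower in muscle of the high lines, a call that the estimated correlation (adjusted p = 0.240) did not make. The exact splits gave an exact permutation p of 0.0238 (adjusted p = 0.337), and 1 list alone could not pass their adjustment. Slides as the whole cause were argued against, because the list median was negative within each of the 6 slides that hold both groups, at −0.53 for the one nearest to 0. The MU pair as the whole cause was argued against too, with a median of −0.57 without both MU lines. Another share of slow muscle in the tissue taken could produce the same values, since 5 slow contractile genes were lower together with a median of −2.68, and no value separates this from a change within fibres. A difference in fibre type through selection stays open as well and was not tested.

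Gluconeogenesis and amino acid catabolism genes leaned lower in liver of the high lines on 23 arrays, a call not made with an estimated correlation (adjusted p = 0.702) or on all 27 arrays (adjusted p = 0.368). More recent feeding of the high lines may contribute, with a median of −0.62 in muscle for 19 genes raised by fasting (19 of 19 lower, exact permutation p = 0.0159). But 16 of these 19 were in lists already seen to be lower, so this test cannot decide. In liver itself 12 of 14 genes raised by fasting there were lower, with a median of −1.09 (exact permutation p = 0.0159). Igfbp1 and Ppp1r3g were among them. So were G6pc and Ppargc1a of the list in question, so this set cannot decide either. Liver genes raised by feeding had a median of −0.15 (exact permutation p = 0.714). Another time of day at sampling cannot be told apart from the groups either, with a clock contrast of 0.98 (exact permutation p = 0.548) while other splits reached 3.56. A lasting difference between lines stays open and was not tested.

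Chance was not excluded for the high against low comparisons by the counts of lists and of genes at an unadjusted p under 0.05, over 100 of the 126 splits of the lines into 5 and 4. For genes that passed the real count was 0 by limma in each (461, 1427 and 1247 at an unadjusted p under 0.05), which all 100 splits reach by construction, so that count says nothing about chance. The highest other count was 5 in liver on 27 arrays, 13 on 23 arrays and 511 in muscle. The muscle split with 511 sets ROHi, EDHi, EDLi and DUHi against the other lines and points to a structure of the samples, whose source was not tested. The arrays of these 4 lines lay on slides 12 to 15, where ROLi lay too, and those of the BE and MU lines on slides 9 to 11. For genes at an unadjusted p under 0.05, 55 splits gave as many on 27 liver arrays (461 real, 2783 highest other), 13 on 23 arrays (1427 and 2106) and 24 in muscle (1247 and 3919). For lists, 57 splits gave as many on 27 liver arrays (14 and 24), 48 on 23 arrays (10 and 18) and 42 in muscle (15 and 26). For selection by tissue the real count of genes that passed was 0 as well, again reached by all 100 splits by construction (highest other 3 on 27 arrays and 2 on 23 arrays), while 59 and 18 splits gave as many at an unadjusted p under 0.05 (421 and 3572, 1184 and 2839). For muscle against liver chance was excluded, with 1 exchange of tissues as large, the real one (8922 against 8315 on 27 arrays, 9772 against 7866 on 23 arrays). The 8 sign patterns of 4 pairs are too few for a share under 0.05; genes changed the same way numbered 47 against 184 for the highest other pattern in liver on 27 arrays (5 patterns as large), 116 against 65 on 23 arrays (1) and 114 against 42 in muscle (1).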

How the results depend on the processing

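The repeats on 23 liver arrays, and those without the 3 arrays of the second scan day or the 4 liver arrays, were chosen after seeing the data. On all 27 liver arrays the extracellular matrix list, lower in the high lines (adjusted p = 0.0184), passed as higher without ROLi (0.0378). Normexp correction added an offset of 50, while the median intensity of an array was 28.3 to 81.3. Such an offset draws the fold changes of dim genes towards 0 by construction. Apart from this, where a value moved the cause was not tested, except where fewer lines or arrays or another size threshold made the alternative.

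Counts of genes for high against low were 0 by limma in the planned analysis. With single arrays and line as a random block they were 4 in liver on 27 arrays, 298 on 23 arrays and 207 in muscle, and with a block for the array number as well 4, 210 and 169. Both fits still count technical arrays towards their precision, while selection varies only between lines. Array numbers did not pair the arrays, since arrays of the same number correlated at a mean of −0.00258 in liver and −0.0154 in muscle across pools. With arrays as independent samples the counts were 377, 2798 and 3230, an analysis that takes technical repeats for replicates. On 23 liver arrays normexp correction with quantile scaling gave 1, quantile scaling 1 and a filter in all lines 2. With each line left out the count was 0 to 4 on 23 liver arrays (4 without BELi, 2 without EDHi, 1 without MUHi or EDLi) and 0 to 6 in muscle (6 without EDHi). Selection by tissue gave 1 gene without the 3 arrays of the second scan day; on 23 liver arrays it gave 1 with a filter in all lines, 1 with trend and robust options and 0 to 2 with a line left out (2 without ROHi).

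With an estimated correlation 0 lists passed in liver on 27 or 23 arrays and 0 in muscle. With a line left out 11 to 25 lists passed in liver on 27 arrays and 6 (without MUHi) to 15 on 23 arrays, and an origin block gave 16 on 23 arrays.

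Genes changed the same way in all pairs numbered, with normexp correction, 11 in liver on 27 arrays, 38 on 23 arrays and 35 in muscle; at 2-fold 13, 33 and 28; and at any size 1330, 3306 and 3579. On liver arrays as labelled a slide block gave 122, leaving out 1 array of each pool 47 to 82, leaving out the 3 arrays 82 and the 4 arrays 116. Counts of genes at least 2-fold apart within a pair, or in DUHi against the low lines, were added over these comparisons and both tissues. The sum, in which a gene can count several times, was 18226 with all 27 liver arrays and 6620 with normexp correction. Muscle against liver gave 5150 genes with normexp correction on 27 arrays and 5735 on 23. Median scaling moved the median of all genes from 0.11 to 0.61 on 23 arrays and from 0.12 to 0.60 on 27 arrays, so that 7783 genes were higher in muscle and 3142 in liver on 23 arrays.

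The correlation of fold changes between tissues passed with no filter on dim probes, at 0.337 on 27 arrays (exact permutation p = 0.0317) and 0.319 on 23 (exact permutation p = 0.0397). With a line left out it was 0.203 to 0.441 on 27 arrays (0.441 without BEHi, exact permutation p = 0.0286) and 0.366 to 0.446 on 23 (0.422 without BELi, exact permutation p = 0.0357).

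Of the genes named for their fold change, 33 of 33 kept their direction under all alternatives run in liver on 23 arrays, 31 of 33 on 27 arrays (not Ghr without ROLi, nor Hpd without EDHi or EDLi) and 32 of 34 in muscle (not Acvr2b without BELi, nor Myh4 under quantile scaling). Single probes of a gene still differed in sign for Igfbp3, Ghr and Hyou1 (−0.44 to 1.21) on 23 liver arrays, and for Igfbp3 on 27. Signal over background limits dim genes, since 59.8% of spots lay well above background on the weakest liver array and 63.6% on the weakest muscle array.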

Other observations

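The tests of genes raised by fasting and of clock genes were chosen only after the results were seen. The 3 of 19 genes raised by fasting in muscle that lie outside the lists of fatty acid oxidation and atrophy had a median log2 fold change of −0.84 in muscle. Clock genes on the Arntl side had a median of 0.41 in liver and those on the Dbp side −0.51 (exact permutation p = 0.563 and 0.413), against 0.06 and 0.00 in muscle.

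Transcripts of liver in the muscle pools followed the level of the gene in the line's own liver, with r = 0.891 to 0.981 across genes in the 7 lines other than MUHi and MULi. In MUHi and MULi r was 0.262 and 0.0409, largely fixed by choosing probes above background on none of their muscle arrays.

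MUHi muscle had the widest spread between arrays of a pool, with a median SD of 0.17 log2 units against 0.05 in DUHi muscle. With all 27 arrays the liver pools of EDHi and ROLi had a median SD of 0.62 and 0.51, against 0.05 to 0.07 in the other 7 pools.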
